A study of Homo sapiens with 8 samples.

How the data were processed

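MicroRNA was measured in K562 cells before and during erythroid induction, on 1-colour arrays with Cy3, per the labels. Cells were first adapted to serum-free StemLineII medium and then induced there with 50 ng/ml interleukin 3 and 7.5 U/ml erythropoietin. Small RNA was isolated and labelled with Ambion kits, per the labels' protocols. The extraction protocol names CD34 cells as the source whereas every other label names K562. The samples were taken to be K562. The scanner, the image software and the background correction are not given in the sources used here.

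The deposited values are linear Cy3 intensity, from which the mean of each array had been subtracted: every column averages 0, and all values of a column share 1 decimal fraction (2 in the day 15 column). The subtracted mean is unknown, so the true zero of each array is unknown, and no scaling between arrays is visible. Between 67.1% and 87.8% of the values of a column lie at or below 0. The column medians were -186 units on day 0, -104 on day 2, -211 on day 4, -116 on day 6, -87.9 on day 8, -66.2 on day 10, -39.3 on day 15 and -17.4 on day 22, and the standard deviations ranged from 1029 on day 0 to 65.7 on day 22. The scale between arrays remains unknown, and so does the zero. All 8 columns were matched to their time points through the sample titles.

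The 621 rows were read as 207 features of 3 consecutive spots. All named genes occupy exactly 3 consecutive rows, and the intraclass correlation of ranks within such sets was 0.867 to 0.973, against 0.407 to 0.628 when the sets were shifted by 1 or 2 rows. Of the rows, 201 had 1 gene symbol, 0 had several and 420 had none. All 201 symbols were matched by gene identifier to the RefSeq annotation of GRCh38.p14 and 0 changed. That annotation served for names and for which genes are neighbours. No coordinates are given, because no genome build is named for the arrays.

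Background was handled with normexp in limma (version 3.58.1, R version 4.3.3) with an offset of 50, followed by log2, quantile normalization between arrays and averaging of the 3 spots. Quantile normalization was used because the array medians after background correction ranged from 6.26 to 8.10 on the log2 scale. The SD between 3 spots was 0.08 to 0.36 on the log2 scale (root mean square per array). Offsets and normexp shrink log2 differences of dim features, so small fold changes are understated there. Level above the dimmest spot of the array is also given, and shares of the day 0 signal take the dimmest spot as zero.

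The trend was tested with limma's lmFit and eBayes on the order of the time points, with 5 residual degrees of freedom, and is given as the fitted change over the 7 steps from the first to the last time point. Fits without day 0 or day 22 keep the factor of 7 steps, so their fitted changes extend beyond the arrays used. Curvature was tested by the second-order orthogonal polynomial, with 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over 207 features with a threshold of 0.05. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01. The similarity of arrays was tested by exact permutation. Differences from day 0 were counted and not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

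The design, tests, gene lists, markers, most alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 features per direction of the trend, filled by smallest p where fewer pass, the 5 with the smallest p per direction of curvature, and up to 10 per direction against day 0. It also takes at most 4 members per list, and the 5 highest mean levels. A choice made after seeing the values was to leave out day 15, which is the mean of 2 other columns, so the trend used 7 arrays and the comparison with day 0 used 6 later ones. Another was normexp in place of the planned floor, which would have set all values at or below 0, most of each array, to the lowest positive value. Both planned versions were run as alternatives. The planned contrast of days 8 to 22 against days 0 to 6 then set 3 arrays against 4. The other alternatives were no normalization, median centring, 75th percentile scaling, a filter at the median level, a pseudocount, other time scales, array weights, each row tested by itself, leaving out each array, other distances, an estimated correlation and limma's fry. Also chosen later were the use of the split at days 8 to 22 as a batch, the shift of the dimmest spot to 50, the combined alternative without day 22, and all limits on brightness and on neighbour distance.

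The trend test was tested on simulated data built from the levels and scatter of these arrays, with 40 of 207 features changed, in 20 simulations per fold size. Simulated changes of 2-fold, 4-fold and 8-fold were called in 1.5%, 23.9% and 49.6% of changed features, with the right sign in 91.6%, 99.3% and 99.1% and with 0, 0.65 and 1.45 false calls on average. Mean fitted log2 changes were 0.86, 1.41 and 1.81 for simulated changes of 1, 2 and 3. The simulation gave all features 1 common scatter, independent between features, and as many rises as falls. That scatter came from values not normalized between arrays, so differences between whole arrays entered it as scatter of single features. The trend test itself used quantile normalized values, so the simulated recovery may be too low. It held no difference of scale between arrays, no narrower range on day 22 and no batch. Its rates of calls and false calls therefore need not hold for these arrays.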

Results

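MicroRNA levels were followed in K562, a human myeloid leukaemia cell line that can be driven towards the red cell lineage, while the cultures were exposed to interleukin 3 and erythropoietin in serum-free medium. Uninduced cells on day 0 served as the baseline, and cells were taken on days 2, 4, 6, 8 and 10, and then on days 15 and 22. Each time point had 1 column of Cy3 values, so no time point had a replicate and the number of arrays limited the precision of every comparison. The labels do not say whether the time points came from separate cultures, so each p-value measures only the scatter between these arrays. The table held 621 rows, which formed 207 features of 3 spots each. Of these, 67 carried a microRNA gene symbol and 140 had no name in the tables used here. A symbol names the gene and not the mature arm. The day 15 values equalled the mean of the day 10 and day 22 values in all 621 rows, so day 15 was left out and the comparisons rest on 7 arrays. The brightest spot lay 15443 units above the dimmest on day 0 and 554 units above it on day 22, while the median spot lay 112 and 63 units above it.

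**Figure D1:**
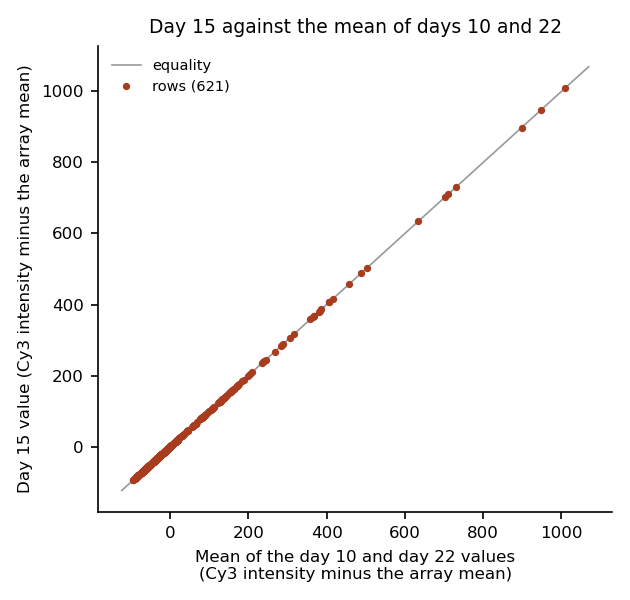
The day 15 value (vertical axis) is plotted against the mean of the day 10 and day 22 values (horizontal axis), both as Cy3 intensity minus the array mean, with 1 point for each of the 621 rows. All points lie on the line of equality, with a largest deviation of 0.005 units.

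MIR20A and MIR21 gave the highest mean signals among named features, at 10.81 and 10.71 on the log2 scale over 7 arrays. Probes differ in affinity, so signals of different features do not rank their abundance. MIR20A belongs to the MIR17_92 cluster, a MYC target that promotes proliferation, and MIR21 is abundant in many tumours. MIR15B at 9.45, MIR33A at 9.35 and MIR18A at 9.32 followed. MIR20A measured 12423 ± 3699 units above the dimmest spot of its array on day 0 (SD, n = 3 spots) and 136 ± 5.86 on day 22, and MIR21 measured 3340 ± 971 and 124 ± 13.5. MIR33A, hosted by an intron of the sterol regulator gene SREBF2, measured 686 ± 36.4 on day 0 and 468 ± 15.4 on day 22. The SD of 3 spots covers spotting and reading only, not cultures or arrays. Of the markers of tissues foreign to these cultures, 6 were measured. MIR429 (epithelial), MIR375 (pancreatic islet) and the embryonic MIR367, MIR371A, MIR372 and MIR373 had mean signals from 6.37 to 7.11. These markers were chosen to show the signal expected without expression. Of the 207 features, 95 had a mean signal above the highest marker, MIR373, and 28 of these were named. Named features at or below that level, such as MIR342, MIR331, MIR424 and MIR10A, are thus not shown to be expressed, and their directions below are to be read so. The neural, muscle and liver lists had no measured member.

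MIR19A fell in the trend test, but the call was lost in some settings, and chance and array batch were not excluded, as given below. This member of the MIR17_92 cluster had log2 levels of 9.73, 9.98, 9.77 and 9.47 on days 0, 2, 4 and 6, then 8.11 on day 8, 8.06 on day 10 and 7.14 on day 22. Its intensity above the dimmest spot was 1160 ± 383 on day 0, 850 ± 87.9 on day 6, 157 ± 24.6 on day 8 and 65.3 ± 5.03 on day 22 (SD, n = 3 spots). Its fitted log2 change from the first to the last time point was -3.02 ± 0.45 (SE, n = 7 arrays, adjusted p = 0.0225, limma trend test with Benjamini-Hochberg adjustment).

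Among 207 features, 1 fell and 0 rose by this limma trend test, while 22 had an unadjusted p under 0.05, of which 10 had positive and 12 negative fitted changes. The named features next in order of p did not pass. On the negative side were MIR18A at -2.01 ± 0.63 and MIR20A at -2.12 ± 0.73 (SE), both from the same cluster as MIR19A, each with an adjusted p of 0.277 in limma after Benjamini-Hochberg adjustment. MIR342, a microRNA of lymphoid and myeloid cells, had a fitted change of -1.10 and MIR15A, a repressor of BCL2, one of -1.27. MIR21 was at -1.26, MIR331 at -0.62, MIR326 at -0.56, MIR93 at -0.55, MIR25 at -0.50, MIR381 at -0.36 and MIR375 at -0.28. On the positive side, MIR328 had a fitted change of 1.96 ± 0.61 and MIR95 one of 0.92 ± 0.32 (SE), each with an adjusted p of 0.277 in limma after Benjamini-Hochberg adjustment. MIR29A was at 1.77, MIRLET7I at 1.55, MIR345 at 1.51, MIR450A1 at 1.41 and MIR26B at 1.27, with MIR346 at 0.995, MIR374A at 0.87, MIR31 at 0.85, MIR448 at 0.68 and MIR98 at 0.60. Of these 12 positive members, all but MIR29A had negative fitted changes when the arrays were not normalized against each other.

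The direction of many features depended on whether the arrays were scaled to each other. Of 44 named genes, 26 had the opposite sign without normalization, against 6 after median centring and 7 after 75th percentile scaling. The median fitted change over 207 features was 0.03 after quantile normalization, -1.24 without normalization, 0.24 after median centring and 0.46 after scaling to the 75th percentile. Without normalization 9 features fell and 0 rose, among them MIR20A with a fitted change of -5.08, MIR19A with -4.63 and MIR18A with -3.64, at adjusted p of 0.0138, 0.0138 and 0.0379 (limma, Benjamini-Hochberg), and 205 of 207 fitted changes were negative. Median centring and 75th percentile scaling each gave 2 features that fell and 0 that rose. The MIR19A call was lost without day 2 (adjusted p = 0.112), day 4 (0.0706), day 10 (0.0564) or day 22 (0.165), on a log2 scale of days (0.439) and with values at or below the array mean set to 1 floor (0.353), all from limma with Benjamini-Hochberg adjustment. Its fitted changes were then -3.01 ± 0.52, -2.84 ± 0.44, -3.02 ± 0.52 and -3.05 ± 0.66 without those days, -2.84 ± 0.73 on the log2 scale of days and -10.52 ± 1.79 with the floor (SE), against -3.02 ± 0.45 with all 7 arrays. The values without 1 day are the slope times 7 steps, so that without day 22 extends the line past day 10, its last array. On this scale the slope stayed near its value without those days. The call was kept without day 0 (adjusted p = 0.0185), day 6 (0.0292) or day 8 (0.0319), all from limma with Benjamini-Hochberg adjustment. Without day 8 the fitted change was -2.84 ± 0.44 (SE), as without day 4, yet the call was kept without day 8 and lost without day 4. The loss thus depended on which array was left out, but not through the slope and SE of MIR19A alone. Its fitted change was negative in all 20 alternatives.

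Within the features, the spots split the arrays into days 0 to 6 and days 8 to 22: among the 30 brightest features, the third spot was brighter than the first in 27, 30, 22 and 24 on days 0, 2, 4 and 6, and in 10, 11 and 10 on days 8, 10 and 22. With a term for this split in the limma trend test, 0 features passed after Benjamini-Hochberg adjustment and 16 had an unadjusted p under 0.05. MIR19A then had a fitted change of -1.52 ± 0.65 (SE, adjusted p = 0.584, limma with Benjamini-Hochberg). Within days 0 to 6 (4 arrays) and within days 8 to 22 (3 arrays), 0 features passed the limma trend test. An unadjusted p under 0.05 was reached by 7 and 63 features. The second fit holds days 8, 10 and 22 only, so its 63 cannot be told apart from a peculiarity of the day 22 array.

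**Figure D2:**
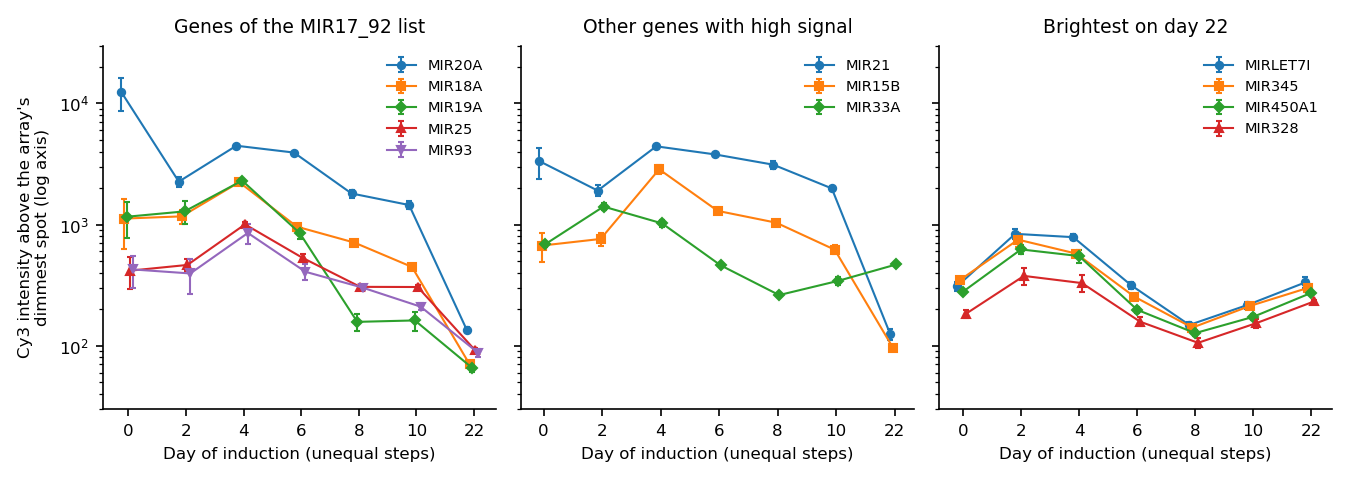
Cy3 intensity above the dimmest spot of the array (vertical log axis) is plotted against the day of induction (horizontal axis, unequal steps) for 12 named features in 3 panels, with points as means and bars as SD of 3 spots on 1 array. MIR20A stood at 12423 on day 0 and 136 on day 22, whereas MIR33A stood at 686 and 468; directions relative to other features depend on the scaling.

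The MIR17_92 list, made of the cluster and its paralogs, had direction down, and its call depended on the test and on day 22. Of its 5 measured members, MIR19A fell, and MIR20A, MIR18A, MIR25 and MIR93 had negative fitted changes that did not pass, with a list median of -2.01. Adjusted over the list alone, 3 members fell. MIR25 and MIR93 are neighbours within an intron of the replication gene MCM7. In limma's camera test with a preset correlation of 0.01 the list had an adjusted p of 0.000265 (Benjamini-Hochberg over 4 lists). The correlation of its members estimated from these arrays was 0.448, and with it the call was lost (adjusted p = 0.217, limma camera with Benjamini-Hochberg). The directional fry test of limma gave an adjusted p of 0.131 and its mixed test one of 0.0474, both by Benjamini-Hochberg. The direction was down under all 4 scalings. Without day 22 the camera test gave an adjusted p of 0.247 (limma, Benjamini-Hochberg). With the term for days 8 to 22, it was 0.00400 with direction down, within days 0 to 6 it was 0.974 with direction up, and within days 8 to 22 it was 0.00216 with direction down (limma camera at the preset correlation, Benjamini-Hochberg). With an estimated correlation these became 0.316, 0.976 and 0.373.

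The ERYTHROID list, of microRNAs known from red cell precursors, had 4 measured members, MIR15B, MIR15A, MIR96 and MIR22, of which 0 rose and 0 fell. Their fitted changes were -0.64, -1.27, 0.18 and 0.04, and the camera test gave an adjusted p of 0.371 (limma, Benjamini-Hochberg). With the term for days 8 to 22 it was 0.0650 with direction down, within days 0 to 6 it was 0.220 with direction up, and within days 8 to 22, on 3 arrays, it was 0.00465 with direction down (limma camera at the preset correlation, Benjamini-Hochberg). With an estimated correlation these became 0.335, 0.796 and 0.373, so 0 passed. The best known red cell microRNAs on that list were not among the named features. The LET7 family, repressors of growth genes such as HMGA2, had 7 measured members, of which 0 rose and 0 fell. MIRLET7I was at 1.55, MIRLET7G at 0.81, MIRLET7E at 0.45 and MIRLET7B at -0.23. The list median was 0.45, and -1.67 without normalization, and the camera adjusted p was 0.371 (limma, Benjamini-Hochberg). The direction of the LET7 list was up after quantile normalization but down without normalization, after median centring and after 75th percentile scaling. With the term for days 8 to 22 the LET7 list had direction up and a camera adjusted p of 0.00168, while the step to days 8 to 22 in the same fit had direction down and one of 0.00378 (limma at the preset correlation, Benjamini-Hochberg). Within days 0 to 6 it was 0.220 and within days 8 to 22 it was 0.00912, both with direction up at the preset correlation. With an estimated correlation the adjusted p was 0.316 for the trend, 0.425 for the step, 0.796 within days 0 to 6 and 0.373 within days 8 to 22, so 0 passed. In the MIR15_16 family MIR15B, MIR15A and MIR424 were measured, 0 rose and 0 fell, and the camera adjusted p was 0.371 (limma, Benjamini-Hochberg). It was 0.547 with the term for days 8 to 22, 0.195 within days 0 to 6 and 0.117 within days 8 to 22.

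The remaining lists had too few measured members for a list test. MIR23A and MIR23B had fitted changes of -0.33 and -0.49, MIR29A one of 1.77, and the megakaryocyte members MIR10A and MIR10B had 0.03 and 0.12. In the MYELOID_LYMPHOID list MIR21 and MIR342 were measured, 0 fell over all features and 1 fell when adjusted over the list alone. Lists of progenitor, MIR30, MIR181 and p53 stress microRNAs had 0 measured members.

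**Figure D3:**
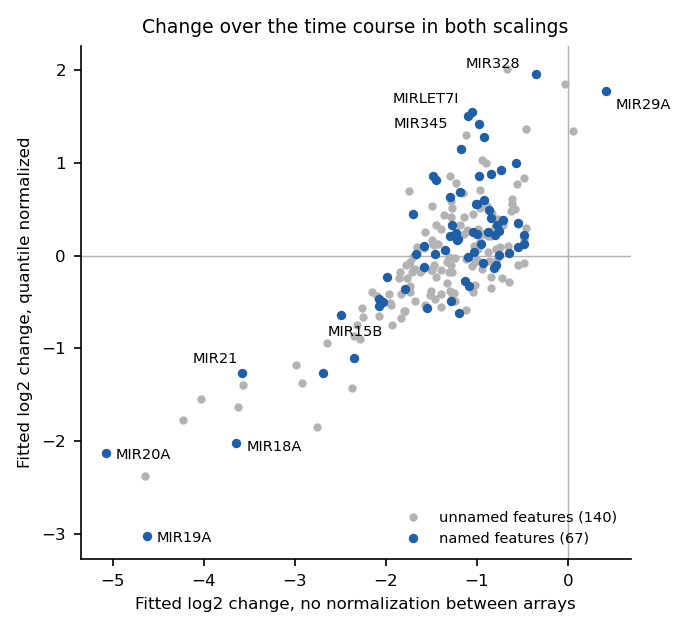
The fitted log2 change over the time course after quantile normalization (vertical axis) is plotted against the change without normalization between arrays (horizontal axis), with 1 point for each of the 207 features. Only MIR19A passed the test after quantile normalization, at -3.02; 205 features lie below 0 without normalization and 100 after it.

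The fit gave MIR15B a peak in the middle of the time course, with log2 levels of 9.20 on day 0, 10.11 on day 4, 10.39 on day 8 and 7.80 on day 22. Its level on day 22 minus that on day 10 was -2.16, so the peak rests in large part on the day 22 array. After quantile normalization MIR328, MIR345 and MIR450A1 had a trough: MIR328 stood at 7.72 on day 0, 7.11 on day 4 and 9.77 on day 22, MIR345 at 8.53, 7.89 and 10.60, and MIR450A1 at 8.21, 7.80 and 10.12. The second-order term of the limma fit had adjusted p of 0.0450 for MIR15B, 0.0265 for MIR328 and MIR345 and 0.0332 for MIR450A1 after Benjamini-Hochberg adjustment. Of 207 features 6 passed, 3 with a peak and 3 with a trough, and 37 had an unadjusted p under 0.05. The other 2 with a peak were unnamed features, starting at rows 85 and 175, and were picked out after their values were seen. The named features next in order of p did not pass: MIR18A, MIR21, MIR15A and MIR22 leaned towards a peak, and MIR374A and MIR26B towards a trough. Without normalization 3 features passed, MIR15B, MIR21 and 1 unnamed feature, all with a peak, and the troughs of MIR328, MIR345 and MIR450A1 did not pass. In that limma fit 21 features had a peak and 0 a trough at an unadjusted p under 0.05. The 10 brightest features of day 22 include these 3. Their mean intensity above the dimmest spot was 373, 789, 678, 292, 164, 231 and 315 units on days 0, 2, 4, 6, 8, 10 and 22. That mean was highest on days 2 and 4, so the trough depended on the normalization. Median centring gave 2 peaks and 0 troughs, and 75th percentile scaling 0 of either. Without day 22, day 4, day 6 or day 8 the count was 0, without day 2 it was 12, and without day 0 it was 48.

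Against day 0, MIR95 was higher at all 6 later time points, by 0.84 on the log2 scale on average, followed by MIR448 and MIR424 at 0.53, MIR31 at 0.51, MIR98 at 0.48 and MIR32 at 0.39. MIR20A was lower at all 6, by -0.99 on average, followed by MIR331 at -0.52, MIR381 at -0.51, MIR93 at -0.50, MIR340 at -0.17 and MIR330 at -0.12. In all, 24 features lay above day 0 throughout and 23 below, where exchangeable arrays would give 14.3%, or 29.6, on each side. A mean difference of at least 1 was reached by 0 of those above and by 3 of those below, none of them named. These differences were counted and not tested. Without normalization 2 lay above and 10 below, after median centring 21 and 24, and after 75th percentile scaling 11 and 26.

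After quantile normalization day 22 had the most features apart from day 0, with 17 features higher and 25 lower by at least 1 on the log2 scale, 9 named on each side. MIR21 stood at 10.69 on day 0 and 8.38 on day 22, and MIRLET7I at 8.34 and 10.83. The 10 brightest features of day 22, which include MIRLET7I, had a mean of 373 units above the dimmest spot on day 0 and 315 on day 22. The higher normalized value of MIRLET7I on day 22 is thus relative to the other features of that array. The counts were 7 higher and 12 lower on day 2, 9 and 4 on day 4, 4 and 1 on day 6, 5 and 4 on day 8, and 4 and 2 on day 10. These are differences between single arrays with no replicate check. Without normalization the counts were 63 higher and 6 lower on day 2, 90 and 1 on day 4, and 0 and 57 on day 22, with median differences of 0.54, 0.86 and -0.62. After 75th percentile scaling they were 2 and 45 on day 2, 3 and 35 on day 4 and 5 and 21 on day 22.

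After quantile normalization, arrays close in time were more alike across the 207 features. The highest correlations joined days 4 and 6 (r = 0.953) and days 8 and 10 (r = 0.952), and the lowest joined days 4 and 22 (r = 0.512). Features are not independent replicates. Over the 21 pairs of arrays, distance rose with the gap in sampling order (rho = 0.499, exact one-sided permutation p = 0.0395 over 5040 orderings). It missed the threshold without normalization, after median centring and after 75th percentile scaling (rho = 0.447, exact permutation p = 0.0639 in each) and with Spearman distance (rho = 0.427, exact permutation p = 0.0613). Within days 0 to 6 rho was -0.216 (exact permutation p = 0.667 over 24 orderings), and within days 8 to 22 it was 1 (exact permutation p = 0.167, the smallest that 6 orderings allow). Without day 22 rho was 0.199 (exact permutation p = 0.228). The relation also missed the threshold without day 2, 4, 6, 8 or 10, with rho of 0.558, 0.413, 0.400, 0.499 and 0.603 and exact permutation p of 0.05, 0.1, 0.0792, 0.075 and 0.0917.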

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

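Both tests in this part were chosen after the result was seen. The day 15 column, which the comparisons do not use, drew attention because its values equal the mean of the day 10 and day 22 values within 0.01 units in 621 of 621 rows. The largest deviation was 0.005 units, whereas the median SD of 3 spots was 9.50 units on day 10 and 6.56 on day 22. A separate hybridisation of day 15 RNA would deviate by at least part of that spot scatter, which the value of 0.005 argues against. The values are consistent with a column computed from the other 2, and half-unit fractions occurred in 293 of its rows. In 168 checks of each column against the mean of each pair of other columns, the next best match held in 2 rows. Why the column holds these values is not given in the sources used here, and no biological explanation was tested.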

How the results depend on the processing

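The settings with all 8 columns, with values at or below 0 set to the lowest positive value (the floor), with the dimmest spot at 50, without day 22 and unnormalized, and with a batch term, at either correlation, were run after the data were seen, of which the first 2 had been planned as the main analysis. The MIR19A trend kept its direction in 20 of 20 alternatives and passed in 13, with adjusted p from 0.00552 to 0.584 (limma, Benjamini-Hochberg). At the preset correlation the MIR17_92 list kept its call in all 18 camera alternatives that include day 22, with adjusted p from 6.32e-07 to 0.0410, and with the batch term (0.00400), but lost it with an estimated correlation. All of these but the last share the preset of 0.01, against an estimate of 0.448, so their agreement does not test that preset. No paired analysis was possible because each time point has 1 column, so the groups share fewer than 2 replicate numbers. On day 22 the median spot lay 63 units above the dimmest and the brightest 554, which limits what that array can show. Unless stated, the cause of a change was not tested.

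The trend count of 1 became 9 without normalization, 2 after median centring, 2 after 75th percentile scaling, 10 with the day as a number (4 up, 6 down), 0 with log2(day + 1), 3 with each row tested by itself, 3 with all 8 columns (2 up, 1 down) and 0 with values at or below 0 set to the lowest positive value. It was 0 without day 22 and normalization, and 0 with the batch term. Leaving out 1 array gave 0 to 4, with 0 without day 2, 4, 10 or 22 and 4 without day 0 (2 up, MIR26B at 2.63 among them, 2 down). The count of 6 curved courses became 3 without normalization, 2 after median centring, 0 after 75th percentile scaling, 10 among features above the median level and 0 with the floor, and 0 to 48 without 1 array. The 47 features on 1 side of day 0 became 12 without normalization, 22 among features above the median level, where fewer are counted, and 12 with the floor. The 94 differences of at least 1 from day 0 became 272 without normalization, 145 after 75th percentile scaling, 182 with the pseudocount and 279 with the floor. The similarity over time had rho 0.447 (exact permutation p = 0.0639) without normalization, 0.447 after median centring and 0.447 after 75th percentile scaling, which by construction leave correlations alone, and 0.427 (exact permutation p = 0.0613) with Spearman distance. Without 1 array it was 0.199 to 0.758, passing only without day 0. The count of 1 list became 0 with an estimated correlation, 0 with directional fry, 2 with the batch term, 0 with the batch term and an estimated correlation, 0 without day 22 and normalization, and 0 to 1 without 1 array.

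For the 44 named genes under 13 other settings, 477 of 554 fitted changes kept direction and side of the threshold, 69 reversed, 5 newly passed and 3 no longer passed. None of the 69 had passed. Without normalization these fitted log2 changes reversed: MIRLET7E -1.70, MIRLET7G -1.44, MIRLET7I -1.06, MIR10A -0.65, MIR10B -0.48, MIR22 -1.04, MIR26B -0.93, MIR31 -0.98, MIR32 -0.87, MIR328 -0.35, MIR33A -1.48, MIR330 -0.76, MIR340 -0.55, MIR345 -1.09, MIR346 -0.57, MIR371A -0.80, MIR372 -0.75, MIR373 -1.23, MIR374A -0.84, MIR424 -0.85, MIR429 -0.999, MIR448 -1.19, MIR450A1 -0.98, MIR95 -0.73, MIR96 -1.21 and MIR98 -0.92. After median centring MIRLET7E -0.22, MIR23A 0.40, MIR23B 0.20, MIR331 0.29, MIR367 0.55 and MIR375 0.35 reversed, and after 75th percentile scaling MIRLET7E -0.0025, MIR23A 0.61, MIR23B 0.41, MIR326 0.16, MIR331 0.51, MIR367 0.77 and MIR375 0.57. With array weights MIRLET7E -0.35, MIRLET7G -0.13, MIR15B 0.45, MIR21 0.92, MIR23A 1.10, MIR23B 0.33, MIR33A -0.39, MIR330 -0.036, MIR372 -0.32 and MIR373 -0.22 reversed. With the batch term MIRLET7B 1.23, MIR10A -0.23, MIR22 -1.14, MIR29A -0.65, MIR326 0.18, MIR340 -0.34 and MIR96 -1.02 reversed. Days 8 to 22 against days 0 to 6 reversed MIR23A 0.38, MIR23B 0.11, MIR330 -0.035 and MIR372 -0.023. The day as a number reversed MIR10A -0.10 and MIR22 -0.31, and log2(day + 1) reversed MIR330 -0.042, MIR340 -0.0017 and MIR96 -0.023. MIR10A was -0.029 with all 8 columns, MIR330 -0.017 with the dimmest spot at 50 and -0.0017 with the pseudocount, and MIR23A 1.39 with the floor.

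Without 1 array, 273 of 308 fitted changes kept direction and side of the threshold, and 30 in 20 genes reversed, 17 of them without day 22. All are the slope times 7 steps, so those without day 0 or day 22 extend beyond the arrays used. The 20 genes are listed next. Their ranges were MIR10A -0.068 to 0.50, MIR15B -1.20 to 1.82, MIR21 -1.95 to 1.75, MIR22 -0.16 to 1.26, MIR23A -0.82 to 1.41, MIR23B -0.99 to 0.63, MIR25 -0.97 to 0.46, MIR26B -0.23 to 2.63, MIR330 -0.18 to 0.12, MIR33A -1.57 to 1.54, MIR345 -0.70 to 2.03, MIR372 -0.20 to 0.43, MIR373 -0.43 to 0.73, MIR374A -0.030 to 1.73, MIR450A1 -0.45 to 1.88, MIR93 -1.07 to 0.19, MIRLET7B -0.72 to 0.028, MIRLET7E -0.71 to 0.70, MIRLET7G -0.57 to 1.13 and MIRLET7I -0.67 to 2.05.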

Other observations

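The tests in this part were chosen after the results were seen, except the counts of other orders and splits of the arrays and the mean correlation of neighbouring genes, whose limit of 10 kb was also set after. MicroRNA genes that lie within 10 kb of each other in the annotation had more similar time courses than other pairs: the mean Pearson r over 7 arrays was 0.490 in 13 neighbour pairs and 0.0616 in 2198 other pairs (one-sided permutation p = 0.002, 9999 resamples), with 12 of 13 positive. MIR25 and MIR93 had r = 0.946, MIR18A and MIR20A 0.939, MIR381 and MIR382 0.828, MIR323A and MIR379 0.784, and MIR424 and MIR450A1 0.566. MIR369 and MIR377, from the same large imprinted cluster as MIR381, had -0.351. Without normalization the means were 0.880 and 0.673. Shared transcription of neighbours could give such values, as a hypothesis. However, MIR371A, MIR372 and MIR373, markers chosen to show the signal without expression, form pairs with r of 0.317, 0.350 and 0.427. MIR323A, MIR369, MIR377, MIR379, MIR381, MIR382 and MIR424 also had mean signals below the highest marker, so they are not shown to be expressed. The mean r of neighbours thus rests partly on such features, and shared transcription cannot be read from those pairs. Order in the table was also related: 174 other pairs whose features lie at most 5 features apart in the table had a mean r of 0.340 (one-sided permutation p = 1e-04, the smallest that 9999 resamples give), while the 7 neighbour pairs farther apart than that had 0.458 (one-sided permutation p = 0.0199).

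MIR29A stood apart on day 10, at 476 ± 94.4 units above the dimmest spot (SD, n = 3 spots), against 113 ± 2.65 on day 8 and 92.7 ± 18.2 on day 22. Without day 22 the fitted changes of MIR21 and MIR15B were 1.75 and 1.82 and that of MIR19A was -3.05 (adjusted p of 0.287, 0.341 and 0.165 in limma with Benjamini-Hochberg adjustment, so none passed). These fitted changes are the slope times 7 steps and so extend past day 10, the last array of that fit. Of the other MIR17_92 genes, MIR18A was then at -0.34, MIR20A at -0.40, MIR25 at 0.46 and MIR93 at 0.19, and none passed. These genes were picked out after their values were seen.

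Features bright on day 0 lost most of their signal by day 22 while others kept theirs. With the dimmest spot taken as zero, of 19 features at 400 units or more above it on day 0, 10 kept under 10% on day 22 and 4 kept over 50%, with a range from 1.09% for MIR20A to 115%. On day 10 the shares ranged from 11.7% for MIR20A to 105%, so part of the loss came before day 22. Of the 25 pairs of the 5 brightest and the 5 dimmest of these on day 0, 15 had the reverse order on day 22 and 0 on each of days 2 to 10. This needs no zero and argues against 1 factor for all signal of the day 22 array alike, such as a lower scanner gain. Among these 19 features, chosen for their brightness on day 0, the order of day 22 was not seen to follow that of day 0 (Spearman rho = 0.0149, 95% bootstrap interval -0.439 to 0.538, permutation p = 0.954), whereas that of day 10 did (rho = 0.726, permutation p = 4e-04). The interval and p-values treat the features as independent, though members of the MIR17_92 list are among them. They measure the spread between features of single arrays, not between arrays or cultures. Across all 207 features the Pearson r between days 0 and 22 was 0.592. Less labelled RNA on day 22 over a background that differs between features could leave such values, as could a change of the RNA. The 10 brightest features of day 22 had a mean of 373 units on day 0 and 315 on day 22. Over the arrays this mean followed the median spot (Pearson r = 0.936, and 0.674 without the 2 farthest arrays). For the 10 brightest of day 0, with 0 shared, the means were 3378 and 111 and r was 0.617. Each mean and the median spot are measured from the same dimmest spot of an array, which alone can relate them. The sets were also picked on these arrays. These values therefore decide for neither reading, and both stay open. A fall of the MIR17_92 list during induction cannot be told apart from a loss of signal on the day 22 array, which is 1 array, since without day 22 the list had an adjusted p of 0.247 (limma camera, Benjamini-Hochberg).

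MIR19A dropped between day 6 and day 8, from a mean log2 level of 9.74 over days 0 to 6 to 8.09 on days 8 and 10, and 2 of 207 features had a larger fall at that step. The same step separates the arrays by the brightness of the third spot over the first. That gradient is beyond random noise between spots on day 0, with 27 of 30 features (exact binomial p = 2.95e-05 after Benjamini-Hochberg over 7 arrays). A change of array batch could contribute to the step of MIR19A, but batch and time cannot be told apart: with both in the limma fit the step had an adjusted p of 0.653 and the trend one of 0.584 (Benjamini-Hochberg). The change of MIR19A with induction stays open as well.

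Other orders of the arrays bear on the trend counts. Of 100 orders, the real one included, 7 gave at least the 1 feature of the real order after quantile normalization, and the highest other order gave 24, so chance was not excluded. A count so far above the real one could reflect a structure of the arrays other than the sampling order, which was not tested. That order had day 22 first or last, as had 4 of the 6 other orders with at least 1 feature and 34 of all 99 other orders, and this difference was not tested. Without normalization 3 of 100 orders gave at least the 9 features of the real one, and the highest other gave 27. This share is under 5%, but 100 drawn orders give it only roughly. As 205 of 207 fitted changes were negative without normalization, the count cannot tell these 9 features from a fall shared by whole arrays. The count of 9 became 0 without day 22, and 0 with the term for days 8 to 22. The highest count of 27 could reflect such a structure as well, but its order did not have day 22 first or last. Of the 35 splits of the arrays into 3 and 4, only the real split of days 8, 10 and 22 against days 0 to 6 gave 1 feature, MIR19A, and the highest other gave 0. This count of 1 split is under 5%, but the split is also that of the spot gradient.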
